A study of Homo sapiens with 6 samples.

How the data were processed

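RNA sequencing was compared between 3 libraries of H1299 cells carrying a mock vector and 3 libraries of H1299 cells carrying a short hairpin RNA (shRNA) against CCNB1, the gene of cyclin B1. H1299 is an established human lung carcinoma line, and the labels' protocols describe selection of stable transfectants with 1 µg/ml puromycin on 14-day post-confluent cultures and growth in 10% serum. Libraries were made from total RNA with the NEBNext Ultra RNA kit and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The deposited tables hold raw counts per gene and FPKM values, per the file headers. Per the submitters' processing notes, bcl2fastq 2.20, HISAT2 2.1.0, featureCounts 2.0.3, DESeq2 and the build GRCh38.p13 were used. The annotation release, the strand setting and the treatment of reads that map to several places were not given in the sources used here, so genes that overlap, or that have near-identical copies, were treated as uncertain. The FPKM deposited by the authors equalled the count divided by gene length and by the library's total, to within 2.4e-09 bases of gene length between columns.

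Every column carried its sample's label, and 0 columns of other samples were present. Groups and replicate numbers came from the sample titles. The counts summed to between 28122665 and 30332989 per library, and 3 counts corresponded to between 0.0989 and 0.107 CPM, the count scaled by library size. Intervals and floors of this kind cover counting error only. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of at least 14.2 for every pair, and all 6 were counted separately.

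Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 17349 of 58336, libraries were scaled by TMM, and knockdown was compared with mock by the quasi-likelihood F test. Adjusted p-values follow Benjamini and Hochberg over the genes tested, with a threshold of 0.05. The common biological coefficient of variation was 17.6%. CPM values are on TMM-scaled libraries, a standard error (SE) of a log2 fold change is the fold change divided by the square root of F, and log2 CPM values used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01, then with a correlation estimated per list and with fry. The 38 lists, with 961 entries, covered the cell cycle, stress and signalling responses, metabolism, matrix and adhesion, lineage states and markers of other cell types. Of those entries, 924 were matched by the symbols in the tables, 35 by current symbols and 2 were not matched. The 34 lists with at least 5 tested members entered the test. The lists, the tests, the threshold and the rule for named genes were fixed before the data were examined.

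That rule named CCNB1, then up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold with a mean of at least 5 CPM in the higher group, groups that did not overlap, and a gene symbol that is not clone-based and not a pseudogene. It added up to 4 members past the threshold per list with a mean of at least 5 CPM in the higher group. It also named CDK1, CCNB2, CCNB3, CCNA2 and CDC25C whatever their result. Some items that the rule or the lists cover are not reported here. Since 4 genes passed the threshold, 24 genes next by p with the same filters, and members of lists, were named as well, and these were chosen after their values were seen.

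Gene positions are those of GENCODE release 29 on GRCh38. The length implied by the deposited counts and FPKM equalled the summed exon length of that release, to within 0.5 bases, for 33609 of the 34493 genes with a count, or 97.4%, and positions are given only for such genes. The longest 3′ untranslated region (UTR) of each gene came from the basic protein-coding transcripts of the same release. Heptamers present in at least 30 genes, 16366 of 16384, were scored over 13188 tested genes with a 3′ UTR of at least 50 bases, CCNB1 left out, from the signed gene statistic after removal of trends with 3′ UTR length, its GC content and expression. Transcript GC content and length came from the longest transcript of each gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for these steps and the plots.

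The tests were tried on simulated counts drawn from the means, spreads and sizes of these libraries. For the comparison of knockdown with mock, over 17012 genes tested, edgeR recovered 73% of 100 genes changed by a log2 of 1 and 99% of 100 changed by a log2 of 2, with 11 false calls. On the same simulated counts, DESeq2 1.42.0 recovered 78% and 97% with 34 false calls over 17349 genes. A list lowered by 0.6 on the log2 scale was the 1 list that camera called among 34. Genes were drawn independently of each other, whereas the correlation estimated in the real data was 0.88 for mitochondrially encoded transcripts. The simulated counts also lack differences that many genes share in single libraries. They therefore cannot show how often camera or the gene tests err in these libraries. A heptamer with a planted shift of 0.5 SD ranked 1 among all heptamers over 13188 genes. A GC trend planted in 3 libraries gave 2069 calls over 17002 genes without a GC offset and 4 with it.

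Alternatives fixed beforehand were DESeq2 size factors or library size alone as the scaling, the DESeq2 test, limma-voom, no filter except genes at 0 everywhere, a filter of 1 CPM in 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM, the replicate number as a block, an adjusted p of 0.01, glmTreat against a fold change of 2, a fold limit of 1.5, and each library left out in turn. Alternatives chosen after the data were seen were the DESeq2 test without knockdown library 2, removal of genes with one heptamer, a term for 2 sets of libraries, and a GC offset. That offset came from a spline of each library's log2 CPM on transcript GC content.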

Results

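The transcriptomes of H1299 cells carrying a mock vector and of H1299 cells carrying an shRNA against CCNB1 were measured by RNA sequencing, with 3 libraries per group. H1299 is an established lung carcinoma line. The series concerns cyclin B1 in lung adenocarcinoma, and its comparison asks which transcripts differ when CCNB1 is knocked down. Mock libraries 1, 2 and 3 held 29545322, 28122665 and 29526518 counts, and knockdown libraries 1, 2 and 3 held 30332989, 28315736 and 29855869. Levels are given as CPM, the count scaled by library size, as mean ± SD over n = 3 libraries, and log2 fold changes are knockdown against mock.

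CCNB1 encodes cyclin B1, the regulatory subunit of the CDK1 kinase that drives entry into mitosis. The gene (ENSG00000134057) lies on chromosome 5 from 69167010 to 69178245, plus strand, in GRCh38. Its transcript was at 307 ± 14.4 CPM (SD, n = 3) with the mock vector and at 22.0 ± 7.10 CPM (SD, n = 3) with the shRNA. It fell 14.0-fold, a log2 fold change of -3.81 (SE 0.22) with an adjusted p of 0.000215 in edgeR's quasi-likelihood test, and ranked 1 by p. Knockdown libraries 1, 2 and 3 held 6.48%, 9.72% and 5.25% of the mock mean, so the target was low in every library labelled as knockdown. A two-sided exact permutation test of the 6 log2 CPM values gave p = 0.1, the smallest that 3 against 3 libraries can give.

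The partners and relatives of cyclin B1 did not pass the threshold. CDK1 (ENSG00000170312, chromosome 10 from 60778331 to 60794852), the catalytic partner of cyclin B1, was at 135 ± 22.3 CPM in mock and 143 ± 48.8 CPM in knockdown libraries, with an adjusted p of 0.889 in edgeR. CCNB2 (ENSG00000157456, chromosome 15 from 59105078 to 59125045), the gene of cyclin B2, was at 163 ± 3.94 and 165 ± 13.3 CPM. CCNA2 (ENSG00000145386, chromosome 4 from 121816444 to 121823933), the gene of cyclin A2, was at 146 ± 2.22 and 130.2 ± 14.9 CPM, with a log2 fold change of -0.16 (SE 0.13). CDC25C, the phosphatase that activates CDK1, was at 35.6 ± 2.197 and 31.8 ± 5.00 CPM, and CCNB3, the gene of cyclin B3, at 2.85 ± 0.481 and 3.14 ± 0.344 CPM. The log2 fold change of CDK1, 0.09, was -0.04 without mock library 1 and -0.24 without knockdown library 1, and the sign of that of CCNB2, 0.01, changed with the scaling and with the libraries used.

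**Figure D1:**
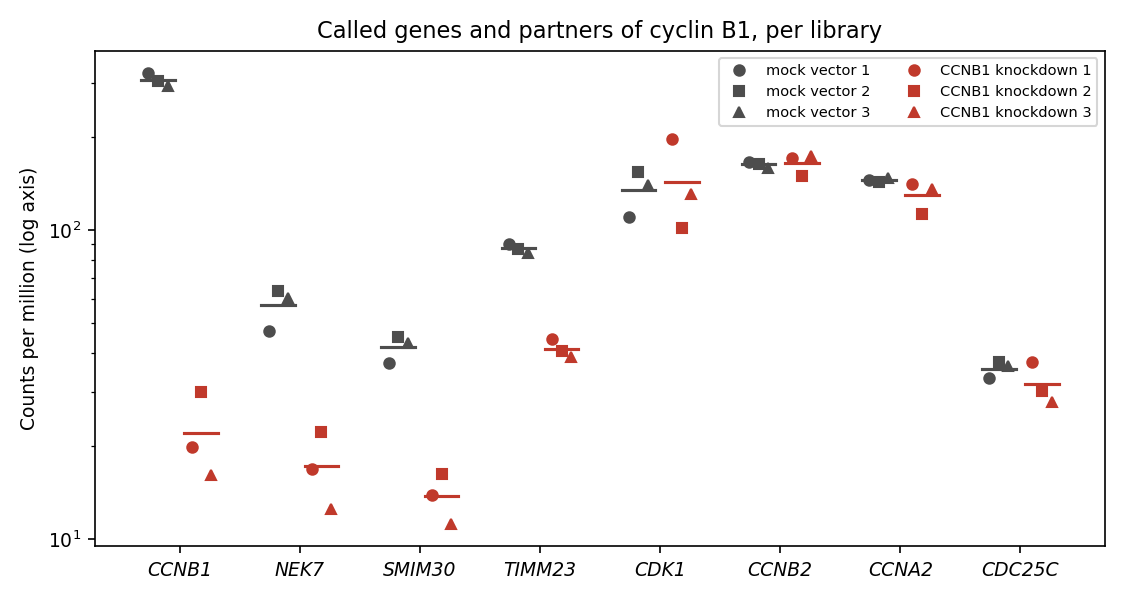
CPM on a log axis (vertical) for the 4 genes past the threshold (CCNB1, NEK7, SMIM30, TIMM23) and for 4 partners or relatives of cyclin B1 (CDK1, CCNB2, CCNA2, CDC25C), with 1 symbol per library and a bar at each group's mean. Each of the first 4 genes was lower in every knockdown library than in any mock library, with CCNB1 at 307 against 22.0 CPM on average, while the group means of the other 4 lay close together.

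Besides CCNB1, 3 genes fell in edgeR's test, each by at least 2-fold. NEK7 (ENSG00000151414, chromosome 1 from 198156963 to 198322420), a kinase known for its roles in the mitotic spindle and in activation of the NLRP3 inflammasome, fell from 57.1 ± 8.57 to 17.2 ± 4.87 CPM, a log2 fold change of -1.73 (SE 0.21) and an adjusted p of 0.0454. SMIM30 (ENSG00000214194, chromosome 7 from 113116718 to 113118613), which encodes a small integral membrane protein, fell from 41.8 ± 4.13 to 13.8 ± 2.51 CPM, a log2 fold change of -1.60 (SE 0.17) and an adjusted p of 0.0202. TIMM23 (ENSG00000265354, chromosome 10 from 45972449 to 46003734), a subunit of the protein translocase of the mitochondrial inner membrane, fell from 87.3 ± 3.06 to 41.3 ± 2.73 CPM, a log2 fold change of -1.08 (SE 0.12) and an adjusted p of 0.0226. TIMM23 has a near-identical copy, TIMM23B, so its counts are uncertain. The longest annotated 3′ untranslated region (UTR) of CCNB1, NEK7, SMIM30 and TIMM23 held the heptamer GTACTAT. Over the 13188 genes whose 3′ UTR was searched, 890 carried it, or 6.75%. No gene rose in edgeR's test at the threshold, against 1413 genes higher and 1193 lower at an unadjusted p under 0.05, and against 175 higher and 384 lower at the threshold in DESeq2, which called the same 4 genes among its 559. The count depended on single libraries: without mock library 1, 2 or 3, or knockdown library 1 or 3, 1 gene, CCNB1, passed, with adjusted p-values of up to 0.273 for NEK7, 0.179 for SMIM30 and 0.273 for TIMM23. Without knockdown library 2, 2453 genes passed, 1107 higher and 1346 lower, 617 of them by at least 2-fold.

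The genes next by p, chosen after their values were seen, were mostly lower in the knockdown, 21 of 24, and did not pass the threshold in edgeR. CDC42, which organizes actin and cell polarity, was at 293 ± 37.3 against 129.9 ± 31.3 CPM, a log2 fold change of -1.17. ACSL4, which activates polyunsaturated fatty acids, was at 208 ± 26.1 against 85.2 ± 27.5 CPM (-1.29), and IPO8, a nuclear import receptor, at 164 ± 9.59 against 70.2 ± 17.1 CPM (-1.23). TMEM123, a cell surface protein, was at 419.8 ± 51.3 against 183 ± 55.0 CPM (-1.20), and SPP1, which encodes osteopontin, at 36.8 ± 6.31 against 12.6 ± 5.17 CPM (-1.55). The 3 higher genes were WNT2B, a Wnt ligand (2.45 ± 0.366 against 5.80 ± 0.277 CPM), MATN2, a matrix protein (2.97 ± 0.381 against 6.86 ± 1.17 CPM), and PLA2G4C, a phospholipase (7.47 ± 0.353 against 13.4 ± 0.601 CPM). Their adjusted p-values in edgeR were 0.0817, 0.0848 and 0.0848. Of the 21 lower genes, 14 carried the heptamer GTACTAT in the 3′ UTR, among them CDC42, ACSL4 and IPO8. Of the 3 higher genes 0 did, which is too few to tell from the 6.75% of all genes searched. Of the 50 lower genes with the smallest p, 54.0% carried it, against 10.6% expected from 3′ UTR length and GC. The heptamer was picked on the same statistic that ranks these genes, so a high share among them is partly built in.

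Gene lists fixed beforehand were tested next. Camera at its preset correlation called 16 of 34 lists, 12 lower and 4 higher in the knockdown, with 18 at an unadjusted p under 0.05. None of the 16 held with an estimated correlation, where the lowest adjusted p was 0.663 and 0 lists had an unadjusted p under 0.05, and fry called 0, with 6 at an unadjusted p under 0.05 and a lowest adjusted p of 0.281. No list member passed edgeR's threshold over all genes tested, and members below were chosen after their values were seen. Adjustment over a list alone, used below, corrects for the members of that list and not for the number of lists. In knockdown libraries 1 and 3 the median of each of the 16 lists lay beyond all 3 mock libraries in the direction called, and in knockdown library 2 that held for 6 lists. The lists were called on these same libraries, so this was partly fixed in advance. Some lists not called also lay beyond the mock libraries in knockdown libraries 1 and 3. Heat shock genes, for example, had medians of 0.48 and 0.31 there, with mock libraries up to 0.0076. Without knockdown library 3, camera called 10 lists.

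Of the immediate early and MAPK feedback genes, 23 of 28 were lower, with a median log2 fold change of -0.50, and 7 fell when adjusted over the list alone (camera adjusted p = 3.25e-09, adjusted p = 0.663 with an estimated correlation). Among the 7 were PHLDA1 (825 ± 84.7 against 339 ± 142 CPM), the ERK phosphatase gene DUSP6 (142 ± 6.32 against 67.5 ± 34.1 CPM) and ETV4, an ETS factor gene (37.6 ± 0.957 against 23.8 ± 1.69 CPM). Of the 7, PHLDA1 and DUSP1 carried the heptamer GTACTAT in the 3′ UTR, and the median of the list stayed at -0.50 without its 4 carriers. Of the integrin and focal adhesion genes, 21 of 26 were lower, with a median of -0.27, and 6 fell when adjusted over the list alone (camera adjusted p = 7.02e-07, adjusted p = 0.663 with an estimated correlation). ITGB1, the beta subunit shared by many integrins, fell from 1411 ± 36.9 to 730.2 ± 265 CPM, ITGA6 from 640.4 ± 46.2 to 365 ± 53.1 CPM, and PXN, the gene of paxillin, from 499.7 ± 25.7 to 323 ± 36.1 CPM.

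Matrix and TGF-beta lists were called lower, with medians from -0.74 to -0.38 in knockdown libraries 1 and 3 and of 0.04 to 0.05 in knockdown library 2. Of the matrix proteases and inhibitors, 17 of 22 were lower, and 5 passed when adjusted over the list alone, 3 of them lower (camera adjusted p = 0.00455, adjusted p = 0.792 with an estimated correlation). PLAU, the gene of urokinase, fell from 346 ± 45.7 to 196 ± 21.5 CPM and MMP14, a membrane-bound metalloprotease, from 238 ± 24.6 to 97.04 ± 60.4 CPM (log2 fold change -1.30, and -1.94 without knockdown library 2), while MMP15 and MMP24 rose to 0.881 ± 0.142 and 2.92 ± 0.961 CPM. Of the collagens and matrix proteins, 16 of 22 were lower, and 4 passed when adjusted over the list alone (camera adjusted p = 0.00455, adjusted p = 0.792 with an estimated correlation). Among them COL18A1 fell from 47.8 ± 10.1 to 27.0 ± 3.83 CPM and LAMA5 from 143 ± 23.1 to 89.8 ± 26.1 CPM, and COL1A1 rose to 1.497 ± 0.571 CPM. Of the TGF-beta target genes, 12 of 19 were lower, and 2 passed when adjusted over the list alone, the receptor gene TGFBR1, which fell from 66.8 ± 6.13 to 33.9 ± 16.0 CPM, and COL1A1, which rose (camera adjusted p = 0.0435, adjusted p = 0.792 with an estimated correlation). TGFBR1 carried the heptamer GTACTAT in the 3′ UTR, and the median of that list, -0.25, was -0.22 without its 3 carriers.

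Cholesterol synthesis, fatty acid synthesis and glycolysis genes had medians below mock in knockdown libraries 1 and 3. Of the cholesterol synthesis genes, 20 of 23 were lower, with a median of -0.47 and 0 past the threshold when adjusted over the list alone, against 11 at an unadjusted p under 0.05 and 4 lower in DESeq2 (camera adjusted p = 3.6e-08, adjusted p = 0.663 with an estimated correlation). The median of that list relative to mock was -0.67 in knockdown library 1, -0.14 in knockdown library 2 and -0.57 in knockdown library 3. FDPS, the gene of farnesyl diphosphate synthase, was at 299 ± 33.5 in mock and 147 ± 71.5 CPM in knockdown libraries. Of the fatty acid synthesis genes, 14 of 22 were lower, and ACSL4 fell when adjusted over the list alone (camera adjusted p = 0.000888, adjusted p = 0.663 with an estimated correlation). Of the glycolysis genes, 20 of 24 were lower, with 0 past the threshold over the list alone, against 1 at an unadjusted p under 0.05 and 0 in DESeq2 (camera adjusted p = 0.0219, adjusted p = 0.792 with an estimated correlation). Their median was 0.11 in knockdown library 2, against -0.49 and -0.25 in libraries 1 and 3.

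Lists of the ATF4, unfolded protein, hypoxia and NRF2 responses were called lower. Of the ATF4 and amino acid response genes, 29 of 30 were lower, with a median of -0.39 (camera adjusted p = 3.57e-08, adjusted p = 0.777 with an estimated correlation). Of the ER chaperone and unfolded protein response genes, 22 of 23 were lower, with a median of -0.28 (camera adjusted p = 2.17e-05, adjusted p = 0.663 with an estimated correlation). No member of either passed when adjusted over the list alone in edgeR, against 7 and 4 at an unadjusted p under 0.05 and 2 and 2 in DESeq2. CEBPG, a dimer partner of ATF4, was at 216 ± 48.7 against 125 ± 46.8 CPM, and HYOU1, an ER chaperone gene, at 149 ± 10.9 against 92.3 ± 26.3 CPM. Of the hypoxia target genes, 21 of 25 were lower, although their median in knockdown library 2 was 0.25 above mock (camera adjusted p = 0.00131, adjusted p = 0.792 with an estimated correlation). When adjusted over the list alone, STC1, the gene of stanniocalcin-1, fell from 402 ± 23.1 to 89.3 ± 70.9 CPM (log2 fold change -2.17, and -3.06 without knockdown library 2), and CA9, a carbonic anhydrase gene, rose to 0.698 ± 0.225 CPM. Of the NRF2 target genes, 17 of 25 were lower, and GCLM and NFE2L2, the gene of NRF2 itself, fell when adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.792 with an estimated correlation). GCLM carried the heptamer GTACTAT in the 3′ UTR, and the median of the NRF2 list, -0.20, was -0.19 without its 4 carriers.

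The lists called higher were epithelial genes, cytosolic ribosomal proteins, mitochondrially encoded transcripts and replication-dependent histones. Of the epithelial genes, 9 of 13 were higher, with a median of 0.49, and 6 passed when adjusted over the list alone, 5 of them higher (camera adjusted p = 0.0219, adjusted p = 0.663 with an estimated correlation). The keratin pair of simple epithelia rose, KRT8 from 336 ± 24.6 to 727 ± 244 CPM and KRT18 from 305 ± 21.1 to 564 ± 170.4 CPM, and KRT19 fell to 0.205 ± 0.130 CPM. KRT8 and KRT18 overlap on chromosome 12, so their counts are uncertain. Of the ribosomal protein genes, 62 of 74 were higher with a median of 0.14 (camera adjusted p = 0.00183, adjusted p = 0.792 with an estimated correlation). Of the mitochondrially encoded transcripts, 13 of 13 were higher with a median of 0.30, and of -0.01 in knockdown library 2 (camera adjusted p = 0.00455, adjusted p = 0.792 with an estimated correlation). Of the histone genes, 17 of 19 were higher with a median of 0.33 (camera adjusted p = 0.0136, adjusted p = 0.663 with an estimated correlation). The median of the histone list was 0.09, 0.46 and 0.29 in knockdown libraries 1, 2 and 3, so the rise was largest in library 2. No member of these last 3 lists passed when adjusted over the list alone in edgeR, against 1, 1 and 6 at an unadjusted p under 0.05 and 0 in DESeq2. Of the 6 histone genes, 5 were higher and 1 lower. Ribosomal protein and histone genes have near-identical copies, so their single values are uncertain.

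**Figure D2:**
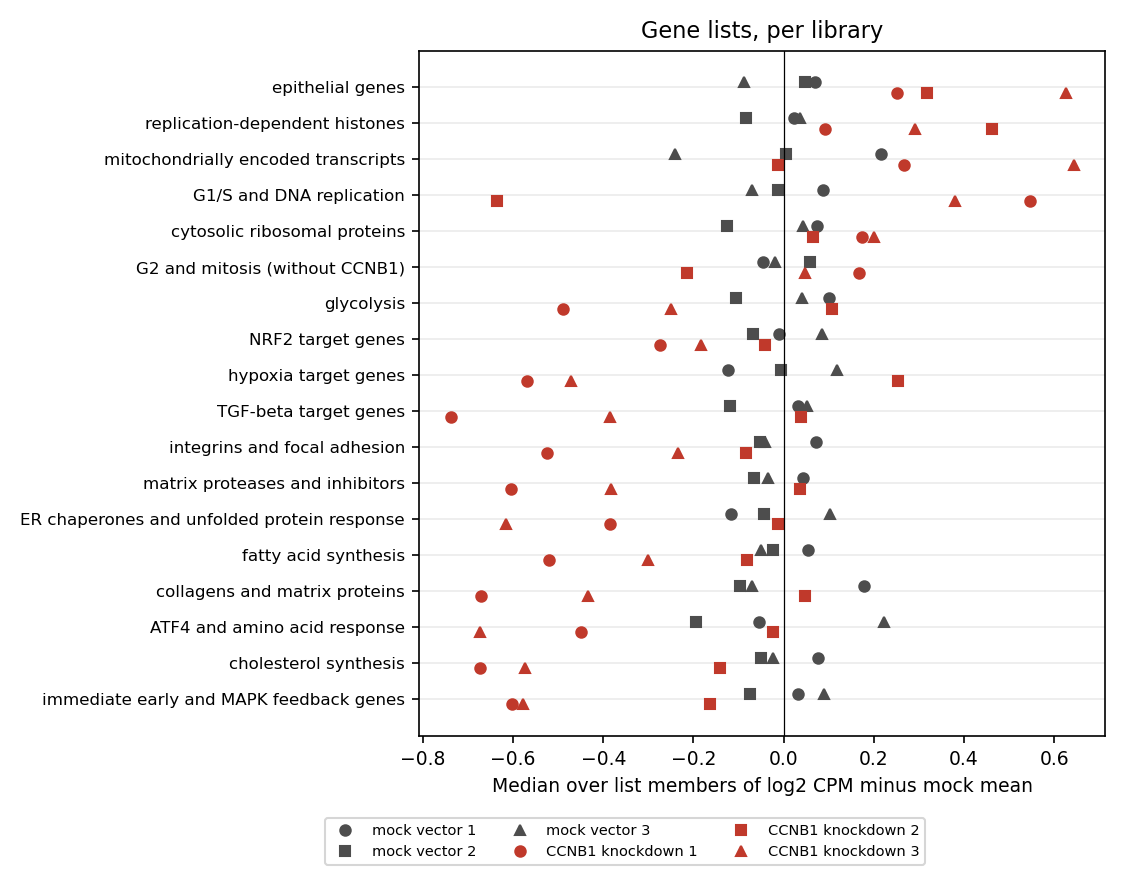
Median over list members of log2 CPM minus the mock mean (horizontal axis), 1 symbol per library, for the 16 lists called by camera and the 2 cell cycle lists. Knockdown libraries 1 and 3 lay beyond the mock libraries in each of the 16 lists, whereas knockdown library 2 did so in 6. The lists were called on these same libraries, so this was partly fixed in advance. For G1/S and DNA replication genes, a list not called, knockdown library 2 lay at -0.64. Knockdown libraries 1 and 3 lay at 0.55 and 0.38 for that list, also beyond the mock libraries.

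Cell cycle lists were not called. Among 40 G2 and mitosis genes without CCNB1, 22 were higher and 18 lower, with a median of 0.02 while camera's direction was down (camera adjusted p = 0.838). Among 38 G1/S and DNA replication genes, 31 were higher, with a median of 0.15 (camera adjusted p = 0.48). No member of either passed in edgeR, also when adjusted over the list alone, against 3 and 3 at an unadjusted p under 0.05 and 0 in DESeq2. The knockdown libraries parted on the G1/S list, whose median relative to mock was 0.55 in library 1, -0.64 in library 2 and 0.38 in library 3, and without knockdown library 2, 22 of its members passed, all higher. Genes of the DNA damage checkpoint and homologous recombination (median 0.05, camera adjusted p = 0.469) and interferon response genes (median 0.01, camera adjusted p = 0.956) were not called, and their tests pointed down against a median above 0. When adjusted over the list alone, the interferon response genes IFI27 and IFITM1 rose to 2.78 ± 0.285 and 0.638 ± 0.105 CPM.

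Further lists were not called either. Among apoptosis regulators (median -0.05, camera adjusted p = 0.529), the pro-apoptotic genes BID and HRK rose and the anti-apoptotic genes MCL1 and XIAP fell when adjusted over the list alone, MCL1 from 812 ± 40.7 to 484 ± 182 CPM and BID from 21.9 ± 1.60 to 37.6 ± 10.2 CPM. Over all genes tested, the adjusted p in edgeR was 0.129 for BID, 0.159 for HRK, 0.174 for MCL1 and 0.115 for XIAP. XIAP carried the heptamer GTACTAT in the 3′ UTR. In the list of NF-kB cytokines and secretory factors (median -0.22, camera adjusted p = 0.188), IL32 rose and PLAUR fell over the list alone. Among Wnt target genes (median -0.22, camera adjusted p = 0.182), CCND1, the gene of cyclin D1, fell over the list alone from 409 ± 37.2 to 271 ± 31.1 CPM. The median of that list was -0.02 without its 3 genes that carry the heptamer GTACTAT in the 3′ UTR. Mesenchymal genes had a median of -0.20 (camera adjusted p = 0.0528), heat shock genes of 0.19 (camera adjusted p = 0.0711), nuclear-encoded oxidative phosphorylation genes of 0.11 (camera adjusted p = 0.117) and MYC and nucleolar genes of 0.13 (camera adjusted p = 0.403). The camera adjusted p was 0.48 for YAP/TAZ target genes, 0.529 for MHC class I antigen presentation, 0.354 for autophagy and lysosome genes and 0.843 for the Notch pathway, whose median of -0.06 and mean of 0.08 differed in sign. Among markers of other cell types, camera gave an adjusted p of 0.825 for 6 fibroblast markers and 0.72 for 6 endothelial markers. Over these lists alone COL1A1, MFAP5 and ESAM rose and DCN fell, at means of up to 2.41 CPM. Markers of leukocytes (2 of 14), alveolar and airway epithelium (3 of 15), squamous and basal epithelium (1 of 10) and neuroendocrine cells (3 of 12) were too few among the genes tested for a list test. The neuroendocrine markers CHGB, from 9.56 ± 1.61 to 15.6 ± 1.15 CPM, and SYP, from 4.23 ± 0.181 to 7.62 ± 0.939 CPM, rose when adjusted over the list alone.

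The libraries did not part by group alone. The first principal component, with 41.8% of the variance, set knockdown libraries 1 and 3 (42.3 and 38.7) apart from mock libraries 1, 2 and 3 (-20.5, -22.6 and -26.7) and from knockdown library 2 (-11.3). Knockdown library 2 correlated with mock library 2 at r = 0.987 across genes, which are not independent replicates, and with knockdown libraries 1 and 3 at 0.979 and 0.978. The median SD of log2 CPM within a group was 0.17 for mock and 0.24 for knockdown. The second component, with 22.5%, had mock libraries 1 and 3 and knockdown library 3 at 24.1, 16.3 and 18.1, and the other 3 libraries between -36.0 and -10.5. Within the first of these sets the log2 difference of CCNB1 between knockdown and mock was -4.25, and within the second -3.64. With a term for the sets, chosen after the data were seen, edgeR called 3 genes, CCNB1, NEK7 and SMIM30. TIMM23 then had an adjusted p of 0.0531, in a range from 5.23e-12 to 0.273 over its alternatives. Its log2 fold change was -1.10 with the term and -1.08 without it. The 16 lists, called on these same libraries, kept the sign of their median within both sets, so this agreement was partly fixed in advance. The sizes differed, with medians in the first and second set of -0.73 and -0.08 for the ATF4 list and of 0.15 and 0.24 for ribosomal proteins. With the set term camera called 17 lists, 14 of them among the 16, without TGF-beta target genes (adjusted p 0.0662) and glycolysis (adjusted p 0.0606). The set term added mesenchymal genes (adjusted p 0.0419), lower, and heat shock (adjusted p 0.0108) and nuclear-encoded oxidative phosphorylation genes (adjusted p 0.0102), higher. These calls are at camera's preset correlation. Without the term, camera's adjusted p with an estimated correlation was 0.792, 0.819 and 0.879 for these lists, in that order. With the GC offset and the preset correlation, camera's adjusted p was 0.042, 0.0434 and 0.167.

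**Figure D3:**
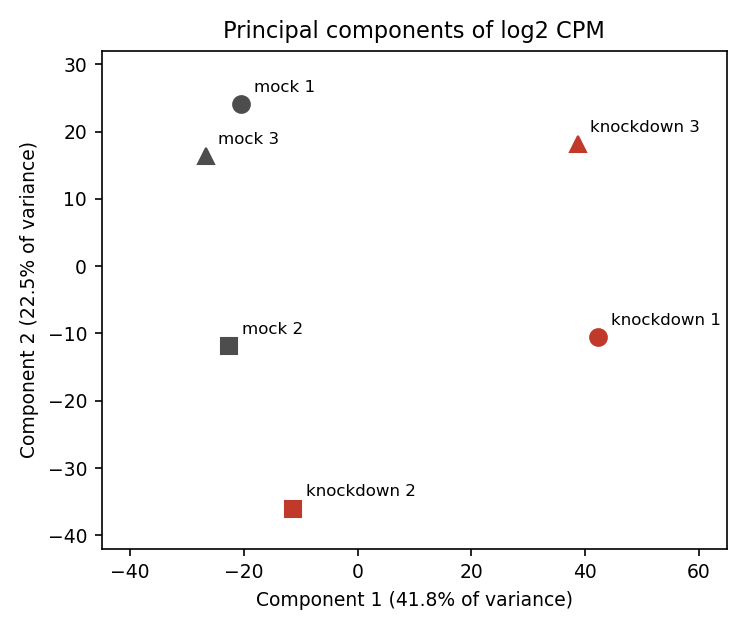
Scores of the 6 libraries on the first component (horizontal axis, 41.8% of variance) and the second component (vertical axis, 22.5% of variance) of log2 CPM, with 1 symbol per library. Knockdown libraries 1 and 3 lie to the right at 42.3 and 38.7, and knockdown library 2 lies on the side of the mock libraries at -11.3.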

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

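The library-set term, the GC offset, the removal of heptamer genes and the DESeq2 test without knockdown library 2 were chosen only after the results were seen. The CCNB1 change kept its direction and its side of the threshold in each of the 17 other settings, with log2 fold changes from -4.09 without knockdown library 2 to -3.63 without knockdown library 3. The 4 genes changed were 2 with library size alone, 559 with the DESeq2 test, 1077 without a filter, 2 with log2(FPKM + 1), 1 with log2(FPKM + 0.1), 1 at an adjusted p of 0.01, 14 with the GC offset and 2795 with DESeq2 without knockdown library 2. Leaving out 1 library gave from 1 to 2453 genes, the highest without knockdown library 2. With the genes that carry the heptamer GTACTAT left out after edgeR's test, 0 genes remained called and 2325 had an unadjusted p under 0.05, since the 4 genes carry it. Of genes changed at least 2-fold, 4 as reported, there were 2 with library size alone, 158 with DESeq2, 359 without a filter, 2 with log2(FPKM + 1), 1 with log2(FPKM + 0.1), 7 with the GC offset, 1 with glmTreat, and from 1 to 617 with 1 library left out. The 16 lists were 0 with an estimated correlation (0 at an unadjusted p under 0.05), 0 with fry (6 at an unadjusted p under 0.05), and from 10 without knockdown library 3 to 22 without knockdown library 2. With the replicate number as a replicate block 162 genes passed, 118 of them by at least 2-fold, and 18 lists. The deviations of same-numbered libraries correlated at -0.19, 0.11 and 0.07, not all over 0.1, so the numbers were not taken to pair the libraries. The CDK1 log2 fold change ranged from -0.238, without knockdown library 1, to 0.278, without knockdown library 2, and was -0.0435 without mock library 1. The CCNB2 log2 fold change was -0.00568 with DESeq2 size factors, -0.0190 with the DESeq2 test and -0.0284 without a filter, and with 1 library left out ranged from -0.0436, without knockdown library 1, to 0.0739, without knockdown library 2, with -0.00626 without mock library 3 and -0.0322 without knockdown library 3. Over all named genes but CCNB1, 1352 values kept direction and side of the threshold, 230 passed it newly, 25 no longer passed and 8, those above, reversed. Most of the 1352 values come from genes that had not passed. All 25 losses came from NEK7, SMIM30 and TIMM23, the only ones of these genes that had passed, each in 17 other settings. The cause was not tested for these changes. At these depths 3 counts amount to 0.0989 to 0.107 CPM, which limits genes near that level.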

Other observations

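The tests of 3′ UTR length and composition, of the pick among heptamers and of genes matched on 3′ UTR length and GC, the admixture test, the test of a batch of libraries numbered 2, and both tests of the library sets were chosen only after the results were seen. Some genes, chosen after their values were seen, differed more between knockdown libraries than between groups. SCD, the desaturase that makes monounsaturated fatty acids, was at 6464, 6955 and 6649.5 CPM in mock libraries 1, 2 and 3, at 1229 and 1512 CPM in knockdown libraries 1 and 3, and at 8374 CPM in knockdown library 2. MCM6, a subunit of the replicative helicase, was at 235 and 225 CPM in knockdown libraries 1 and 3 and at 101 CPM in knockdown library 2, against 122, 113 and 87.7 CPM in mock libraries. The cyclin-dependent kinase inhibitor gene CDKN1A was at 81.0 and 79.4 CPM in knockdown libraries 1 and 3 and at 139 CPM in knockdown library 2, against 160.2, 143 and 164 CPM in mock libraries. ANKRD1, a YAP/TAZ target that rose when adjusted over its list alone, was at 50.8, 2.30 and 35.3 CPM in knockdown libraries 1, 2 and 3, and in knockdown library 2 lay within the mock range of 1.97 to 2.94 CPM. Without knockdown library 2, 16 of 23 cholesterol synthesis genes and 18 of 30 ATF4 and amino acid response genes passed over all genes, all lower.

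Transcripts with few counts were detected more often in the knockdown. Genes with a count numbered 27903, 27643 and 26596 in knockdown libraries 1, 2 and 3, against 25762, 26060 and 25896 in mock libraries 1, 2 and 3. Over 5169 silent genes inside introns of expressed genes, knockdown libraries held 87.3, 86.3 and 58.9 CPM per Mb and mock libraries 51.7, 59.4 and 52.0, so knockdown library 3 lay within the mock range. Over 7624 silent genes at least 10 kb from other genes, the gain per Mb between group means was 0.097 of that inside introns. The 95% bootstrap interval of that ratio, 0.073 to 0.124, does not cover the spread between libraries. Over these distant genes knockdown library 3 lay above the mock range, unlike inside introns, so the ratio mainly describes knockdown libraries 1 and 2.

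Genes with the heptamer GTACTAT in the 3′ UTR were lower in the knockdown, with a median log2 fold change of -0.18 over 890 genes, -0.30 with 2 or more copies and 0.02 with neither the heptamer nor a hexamer of it. Its z of -17.8 was the lowest of 16366 heptamers tested, against a largest size of 4.68 in 100 permutations. Some heptamers absent from the CCNB1 3′ UTR also exceeded that size, such as GTGTCAC at 5.27 and GAAACCC at 4.83. The permutations may therefore give too narrow a bound. Length and GC of the 3′ UTR left -0.16 of a difference of -0.19. The permutation p within strata was 0.0001, the smallest that 10000 draws can give, but these draws did not repeat the pick of the heptamer. It occurs once in the CCNB1 3′ UTR (chromosome 5, 69177651 to 69177657, GRCh38), within AACTTGAGTTGGAGTACTATA (69177638 to 69177658), so a candidate explanation is pairing of these transcripts with the seed of the shRNA's guide, whose sequence was not given in the sources used here. The criterion fixed before the result was not met, since the difference in knockdown library 2, -0.0855, lay within the mock libraries' range, which reached 0.16 in size. That criterion was judged wrong because the mock range shrank to 0.0163 in size within strata of 3′ UTR length and GC, where knockdown libraries 1, 2 and 3 differed by -0.19, -0.11 and -0.19, and genes that carry the heptamer, such as NEK7, SMIM30, TIMM23 and the list members ACSL4, DUSP1, GCLM, PHLDA1, TGFBR1 and XIAP, may be off-targets of the shRNA, which a second hairpin would test.

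Knockdown library 2 lay apart from the other knockdown libraries although its CCNB1 was at 9.72% of mock. The mock share it would need was taken over 1720 genes past edgeR's threshold without knockdown library 2, at a mean of at least 5 CPM. Carriers of the heptamer GTACTAT, which were lower than mock in knockdown library 2 as well, were left out. The median share was 93.5% (95% bootstrap interval 90.6% to 95.7%, genes drawn as if independent), against the 9.72% that the CCNB1 of knockdown library 2 allows. Choosing genes without that library can raise the share, and leaving out the carriers, which stayed low in that library, can raise it too. Over the 1720 genes the distance argues against an admixture of cells with mock-level CCNB1. A batch shared by every same-numbered pair is argued against by the lowest correlation of their deviations, -0.19 for number 1, but libraries numbered 2 correlated at 0.11, so a batch of these alone stays open, since pairs with different numbers reached 0.30. A difference in culture state between the knockdown libraries stays open and was not tested.

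Mock libraries 1 and 3 and knockdown library 3 differed from the other 3 libraries in 42 genes, all higher in that set, against 4 genes between the groups, which points to a structure of the samples that crosses the groups. FTH1, the gene of the ferritin heavy chain, was at 197, 220.0 and 174 CPM in that set and at 7.80, 6.83 and 8.59 CPM in the others, and it has pseudogene copies, so its counts are uncertain. The 42 genes had a median transcript GC content of 64.1% against 48.1% for all genes (central 95% of 10000 random sets up to 52.6%) and a median length of 1215 bases against 3124 (random sets from 2370). A difference in the capture or counting of GC-rich or short transcripts is a candidate explanation, and with the GC offset 10 of the 42 genes still passed, FTH1 among them, while length was not corrected for. No biological explanation was tested. Across genes the knockdown's log2 fold change did not follow GC content (r = 0.0049), but trends of single libraries can cancel in that value. Over genes with a GC content above 60%, knockdown library 1 lay below knockdown library 3, and mock library 2 below mock library 1. With the GC offset, 14 genes passed between the groups, against 4 without it.

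The 6 libraries can be split in 10 ways, too few for a share under 0.05. Of these, 2 gave at least as many genes as the real 4, the highest other being 42, and 2 gave at least as many 2-fold genes as the real 4, the highest other being 41. For lists, 4 gave at least as many as the real 16, the highest other being 23.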
